A study of Homo sapiens with 8 samples.

How the data were processed

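MicroRNAs were measured by reverse transcription and TaqMan quantitative PCR on arrays of 2 cards (A and B) in 4 human lung adenocarcinoma cell lines. Each line gave 1 control sample and 1 sample treated with TGF-β1 at 5 ng/ml for 72 h, so there were 8 samples, 4 per group. Per the labels' protocols, cells grew in RPMI medium with fetal bovine serum, total RNA was extracted with TRIzol, and the PCR ran for 40 cycles. The labels also say that the authors did not authenticate the lines themselves. The instrument software and its baseline and threshold settings are not given in the sources used here.

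The group of each sample was taken from its treatment characteristic, which goes with its title. The source name of all 8 samples words the exposure the other way round and was not used. The authors' deposited fold columns divide the samples titled as treated by those titled as untreated, which is the direction used here.

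The deposited tables hold 3 kinds of values for 754 assays, 377 on each card. The first is the raw threshold cycle (Ct), with no normalization, in which 1 cycle less stands for a doubling and an assay that did not amplify is listed at 40. The second is a linear ratio, which the authors calibrated to the A549 control sample, per the file headers. Recomputing it from the Ct values, as the Ct minus the card's average U6 Ct and with 40 kept as a value, gave the deposited ratio with a largest log2 difference of 4.07e-06. The third is the deposited fold of the treated over the control sample of each line, which equals the quotient of those ratios. The cards also carry U6 in 4 wells each, RNU44, RNU48 and a plant microRNA as a negative control. The plant assay was at 40 in all 8 samples. Assay names are those of the card design, and # marks a passenger strand.

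From the raw Ct values, a Ct above 35 counted as not detected and was set to 35. Each sample and card was normalized to its mean Ct over the assays at 35 or below in all 8 samples, 117 on card A and 51 on card B. The log2 change is the difference of the normalized values, TGF-β1 minus control. Where one sample of a line did not detect an assay, the change is a bound, written as at least. Where neither did, the line gave no difference. The design was fixed before the data were examined, as were the microRNA lists, the rule for naming microRNAs and all alternatives except 2. Over the lines, assays with a difference in at least 3 lines were tested with limma 3.58.1 in R 4.3.3 on the within-line differences, with a moderated test, Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. The cell line thus served as a block. The pairing comes from the cell line in the labels, and over 168 assays the deviations of the control and treated samples from their group means correlated within a line at r = 0.92 in A549, 0.81 in LC2/ad, 0.94 in PC3 and 0.92 in PC9. The highest r with a sample of another line was 0.79 for A549 and LC2/ad and -0.13 for PC3 and PC9, so these values hardly set the LC2/ad pair apart. Nothing in the labels says that a condition was cultured more than once in a line, so the spread tested is that between lines, and within a line there is no replicate.

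Within a line, assays at Ct 32 or below in both samples were counted when they differed at least 2-fold, because higher Ct values rest on few template copies. An assay was called switched when it had a Ct of 32 or below in one sample and above 35 in the other. Theme lists with 3 or more assays that had a difference in all 4 lines were tested with camera from limma, with a preset correlation of 0.01 and again with an estimated one, and with an exact sign-flip test over the 4 lines. The per-line median of each list was placed among 10000 random lists of the same size matched on mean expression. Differences between lines were tested with a limma F test in a model of line and treatment, on the assays detected in at least 1 sample. The lists covered the 14q32 microRNAs, miR-200 with miR-205, microRNAs described as raised by TGF-β, the miR-17 cluster with its paralogs, let-7, miR-29, miR-30, miR-34 with miR-449, the miR-183 cluster, miR-15 with miR-16 and their relatives, miR-23 with miR-27 and miR-24, miR-146, miR-221 with miR-222, the placental C19MC cluster and markers of blood, muscle, fibroblasts and smooth muscle, nerve, endothelium and liver. The 14q32 list includes microRNAs that the study named from these samples, so its change is not independent evidence.

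The named microRNAs were those past the threshold and, with fewer than 20 of these, the 10 largest mean rises and 10 largest mean falls among tested assays with 1 sign in all lines. The rule added miR-134, miR-487b, miR-655, miR-21 and the miR-200 family with miR-205. It further took the 4 largest rises and falls and up to 3 switched assays in each line, up to 4 examples per list, and the 12 assays with the smallest p between lines. On simulated data with noise near the median SD of the test over the lines (250 assays, 20 changed at each size), the fit recovered 60.5% of changes of 1 log2 unit and 99.5% of changes of 2 log2 units, with 3.98% of its calls false. The simulated noise was independent between assays, with SDs spread around 0.54, and held no bounds. These shares do not carry over to assays with a wider spread, such as miR-135b (SD 1.81), so a lack of calls does not exclude large changes.

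The alternatives were other normalizers (the control RNAs, U6, RNU48, a median, 1 value for both cards), the authors' deposited ratio, Ct limits of 32 and 38 for detection and of 30 and 35 for counting, 2 other filters, trend and robust settings, no block, and leaving out each line. Averaging A549 and LC2/ad into 1 line, and a single detection floor for all samples of a card (the highest of the 8) in the test between lines, were chosen after seeing the data. Positions of microRNA genes come from a RefSeq gene table (assembly GRCh38.p14) and serve only for their order, since the arrays' files name no genome build.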

Results

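The data are microRNA levels in A549, LC2/ad, PC3 and PC9, 4 human lung adenocarcinoma cell lines, each with 1 control sample and 1 sample exposed to TGF-β1, a cytokine that drives epithelial cells towards a mesenchymal state. PC9 carries an activating EGFR mutation, and the PC3 used here is a lung line by its labels that shares its name with a prostate line. The series title names miR-134, miR-487b and miR-655 and asks about the epithelial-mesenchymal transition. Of the 754 assays on the 2 cards, 372 were detected at a Ct of 35 or below in at least 1 sample, 168 in all 8 and 382 in none. The control and TGF-β1 samples detected 249 and 256 assays in A549, 281 and 261 in LC2/ad, 272 and 271 in PC3, and 225 and 231 in PC9. The lowest Ct of a microRNA lay between 18.4 and 20.5 in the 8 samples. No culture was replicated within a line, so values of single lines carry no replicate error.

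The first comparison asked which microRNAs differed after TGF-β1 over the 4 lines. The largest mean increase was that of miR-135b, with a log2 change of 2.31 (SE 0.73, n = 3 lines). It was 2.45 in A549, at least 4.05 in LC2/ad and 0.44 in PC9, with no detection in PC3. miR-429, a member of the miR-200 family that represses the ZEB transcription factors and so maintains the epithelial state, had a mean of 1.72 (SE 0.45, n = 4). Its values were 2.39 in A549, at least 2.93 in LC2/ad, at least 1.06 in PC3 and 0.51 in PC9. miR-323-3p of the 14q32 cluster had 1.58 and miR-483-5p, encoded in an intron of IGF2, had 1.57 (n = 3 each). The PC3 values of both and the A549 value of miR-483-5p are bounds. On the other side, 1 of the 2 miR-629 assays had a mean of -1.34 (n = 3) and the other -0.66 (n = 4), miR-361-3p had -1.24, miR-33a#, the passenger strand of the SREBF2 intronic microRNA, -1.22, and miR-204, an epithelial microRNA, -1.17. Bounds enter the means of miR-361-3p (in LC2/ad, PC3 and PC9), miR-204 (in A549 and PC9), miR-33a# (in PC9) and the miR-629 assay at -1.34 (in A549).

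None of these passed the test. Of 250 assays tested with limma, 0 were past an adjusted p of 0.05, the smallest adjusted p being 0.290. An unadjusted p under 0.05 was reached by 30 assays, 15 higher and 15 lower, where 12.5 would be reached by chance. The change had 1 sign in all lines with a value for 61 assays, 21 higher and 40 lower, against 37 by chance, with bounds counted by their computed sign. The 37 takes the lines as independent and both signs as equally likely, but the changes of A549 and LC2/ad correlated (r = 0.50, 150 assays). With U6 alone as the normalizer, the count past an adjusted p of 0.05 was 2, with miR-135b at 2.58 (adjusted p = 0.000637, limma) and miR-429 at 1.98 (adjusted p = 0.00130, limma). That scaling also moved the median of all tested assays from -0.08 to 0.13, and the split of assays under an unadjusted p of 0.05 from 15 higher and 15 lower to 27 and 5. All the other settings tried gave 0.

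The median SE over the tested assays was 0.27. Further mean changes on the higher side were 1.32 for miR-1269, 1.12 for miR-200a, 1.10 for miR-27a#, 1.07 for miR-181a-2#, 0.95 for miR-455-5p and 0.91 for miR-190. Those on the lower side were -1.22 for miR-636, -1.15 for miR-941, -1.04 for miR-192#, -0.83 for miR-107, -0.83 for miR-503 and -0.79 for miR-671-3p. The means of miR-190 and miR-503 rest on bounds alone. Bounds also enter those of miR-1269 (in PC9), miR-636 (in A549), miR-941 (in PC3), miR-192# (in PC9) and miR-107 (in LC2/ad and PC9). Single values turned with the scaling. In PC9 those of miR-941 and miR-671-3p were negative but 0.55 and 0.65 with all control RNAs. miR-1269 in LC2/ad had 0.16 but -0.04 with RNU48, and miR-27a# in PC3 had 0.15 but -0.23 with the median normalizer. The PC9 values of miR-361-3p, miR-33a# and miR-503 are bounds, which moved to 0.04, 0.04 and 0.61 with all control RNAs. miR-361-3p and miR-33a# were detected there only in the control sample, so 0.04 is an upper limit and not a rise. miR-503 was detected in PC9 only after TGF-β1, so its value there is a lower limit and does not show a decrease. miR-21, a microRNA whose processing TGF-β promotes in other cells, gave 0.81 in A549, -0.74 in LC2/ad, 0.13 in PC3 (-0.08 with RNU48) and 1.21 in PC9, a mean of 0.35 (SE 0.36, adjusted p = 0.697, limma).

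**Figure D1:**
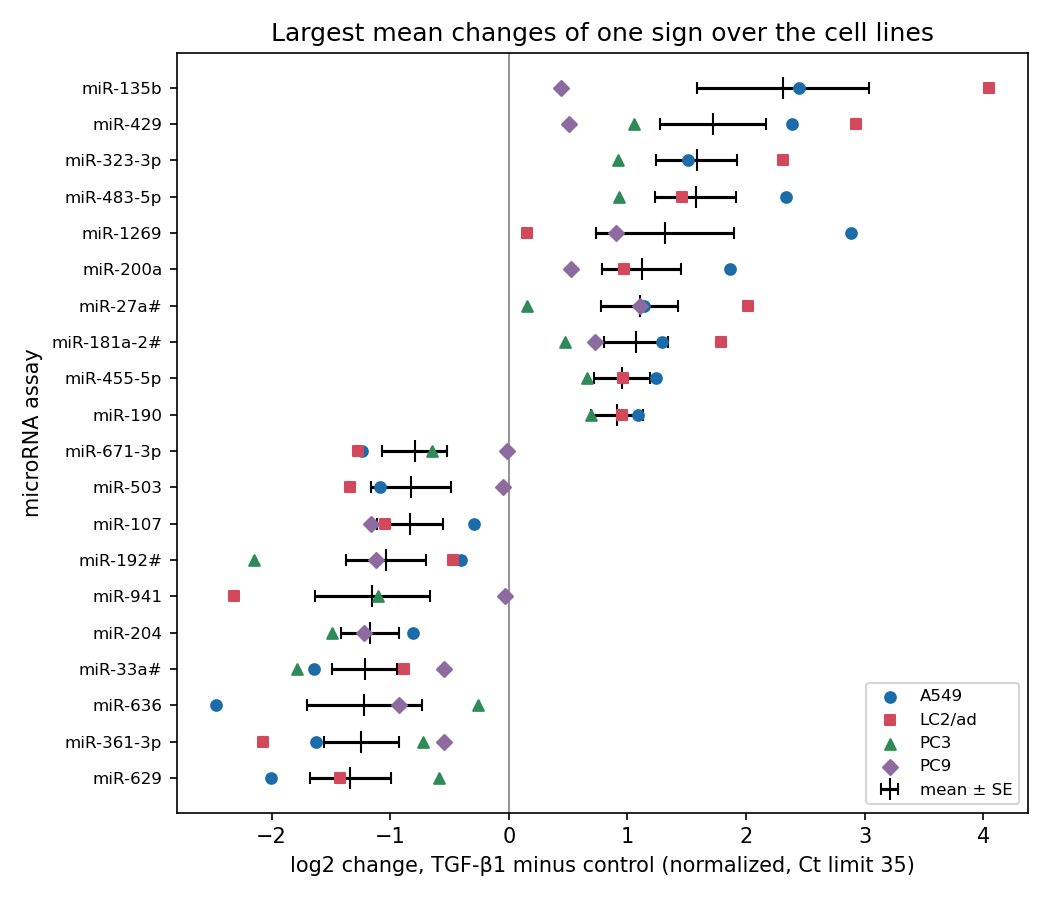
Log2 change after TGF-β1 (x axis) of the 10 largest mean increases and 10 largest mean decreases among assays with 1 sign in all lines that gave a value (y axis), with a point per cell line and the mean ± SE over 3 or 4 lines; points of assays detected in only 1 sample of a line are bounds. miR-135b lies at a mean of 2.31 and miR-429 at 1.72, with the A549 and LC2/ad points above those of PC9, and no assay passed the adjusted threshold. The PC9 point of miR-503 is a lower bound and does not show a decrease.

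The fixed lists of microRNA families were compared with all other assays over the lines. The miR-23, miR-27 and miR-24 list, whose members come from 2 related clusters, rose as a group in the test with a preset correlation, through miR-27 and miR-24 assays alone. The mean log2 change of the 5 assays tested was 0.69 (SD 0.50 over 4 lines), against -0.03 for all 204 assays in that test (camera from limma, adjusted p = 0.00255), and the call was lost with an estimated correlation (adjusted p = 0.581). miR-27a# had 1.10, miR-27a 0.91, miR-24-2# 0.61, miR-24 0.45 and miR-27b 0.38, with 0 members past the threshold over all assays or adjusted over the list alone. The exact sign-flip test gave p = 0.12, the smallest 4 lines allow. miR-23b, which had a value in 3 lines and so was not in the test, had a mean of -0.26 (adjusted p = 0.705, limma). The list's median lay at percentile 99.95 of matched random lists in A549 and 99.92 in LC2/ad, at 85.9 in PC3 and 67.2 in PC9.

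The miR-200 family with miR-205 did not pass (mean 0.58 for 3 assays, adjusted p = 0.365, camera), and its members went different ways. miR-200a and miR-200b, which share a transcript with miR-429, had 1.86 and 0.67 in A549, 0.97 and 1.65 in LC2/ad, and 0.53 and 0.09 in PC9, where they had 1.43 and 0.99 with U6 and 0.32 and -0.12 with the median normalizer. In PC3 miR-200b was detected only in the control sample and miR-200a in neither. miR-200c, from the other cluster of the family, lay lower in all 4 lines, at -0.31 in A549, -0.98 in LC2/ad, -0.40 in PC3 and -0.22 in PC9 (mean -0.48, SE 0.21, adjusted p = 0.416, limma), but its PC9 value turned to 0.68 when scaled to U6, 0.37 with RNU48 and 0.44 with all control RNAs. miR-141, its neighbour, had a mean of -0.02 over 3 lines that turned positive under 5 other settings. miR-205 was detected in PC9 alone, with -0.90, or 0.00250 when scaled to U6. Among passenger strands, miR-200a# was detected only after TGF-β1 in A549 and only in the control sample in LC2/ad, and had 1.88 in PC9, where miR-141# and miR-200c# were detected only after TGF-β1. Adjusted over the list alone, 0 of the 6 tested members passed.

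No other list passed. Means were 0.39 for 4 miR-29 assays (adjusted p = 0.136), 0.32 for 4 assays of the miR-183 cluster (adjusted p = 0.136), 0.15 for 7 let-7 assays (adjusted p = 0.234), -0.16 for 17 assays of the proliferation-linked miR-17 cluster and its paralogs (adjusted p = 0.174), -0.16 for 7 miR-30 assays (adjusted p = 0.326) and -0.14 for 3 assays of miR-221 and miR-222 (adjusted p = 0.792, all camera from limma). Without LC2/ad the means were 0.23 for miR-29, 0.14 for the miR-183 cluster and 0.27 for miR-200 with miR-205, the last over 4 assays in place of 3. That of the miR-17 list was -0.27 without PC3 and -0.07 without PC9, and that of miR-221 and miR-222 was -0.27 without PC3 and -0.09 without A549. With U6 these 2 lists had 0.04 and 0.07, against 0.18 for all assays. The miR-17 list had 14 of 18 members lower in A549, 15 of 18 in LC2/ad, 14 of 18 in PC9 and 8 of 20 in PC3, and its LC2/ad median of -0.35 lay at percentile 1.25 of matched lists. With the median normalizer that median was -0.08 and 10 of 18 members were lower, and with U6 the A549 median went from -0.23 to -0.03, also with 10 of 18 lower. The PC9 median of -0.21 turned to 0.60 when scaled to U6, 0.38 with RNU48 and 0.41 with all control RNAs, and that of PC3, 0.06, to -0.14 with RNU48 and -0.08 with all control RNAs. The list of microRNAs described as raised by TGF-β had a mean of -0.09 and a median of -0.13, both under the -0.03 of all assays, while its test pointed up (adjusted p = 0.985). The miR-15 and miR-16 list had a mean of -0.03, just above all assays, a median of -0.06 and a test that pointed down (adjusted p = 0.885). Adjusted over the list alone, 1 of only 3 tested members of the 14q32 list, miR-323-3p, passed (adjusted p = 0.0216, limma), and 0 members of each other list. Over all assays its adjusted p was 0.290. The 14q32 list includes microRNAs that the study named from these samples, so this pass is not independent evidence. The 14q32, miR-34, miR-146 and C19MC lists had too few assays measured in all lines for the test over lines.

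Within each line the changes were counted over assays at Ct 32 or below in both samples. LC2/ad had 20 assays at least 2-fold higher and 11 lower of 167, A549 8 and 4 of 161, PC9 5 and 4 of 135, and PC3 1 and 0 of 178. The values compare single samples, so no test was made. In A549 the highest were miR-193b at 1.31, miR-27a at 1.28, miR-455-5p at 1.24 and let-7e at 1.15, and the lowest rno-miR-7# at -1.60, miR-375, a neuroendocrine microRNA, at -1.35, miR-939 at -1.29 and miR-1180 at -1.24. In LC2/ad they were miR-27a# at 2.02, miR-539 at 2.00, miR-99a at 1.96 and miR-193b at 1.82, against miR-106b# at -2.15, miR-1180 at -2.00, let-7b at -1.84 and miR-93 at -1.34. In PC9 miR-200a# had 1.88, miR-21 1.21, miR-31# 1.19 and miR-27a# 1.10, while miR-15b# had -1.25, miR-422a -1.23, miR-28-5p -1.15 and miR-339-5p -1.01. In PC3 only miR-27b, at 1.44, reached 2-fold. It was followed by let-7d at 0.87, and by 1 of the 2 miR-550 assays and miR-19b-1# at 0.84, while the other miR-550 assay had 0.39. On the lower side were miR-361-5p at -0.94, miR-324-5p at -0.69, miR-652 at -0.68 and miR-340# at -0.61.

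Switched assays were few. In LC2/ad miR-145 went from a Ct of 35.9 to 31.3 (at least 16.8-fold higher) and miR-135b from 40 to 31.4 (at least 16.5-fold higher), and miR-596 from 31.2 to 40 (at least 11.7-fold lower). miR-331-5p, outside the naming rule and chosen after its values were seen, went from 31.5 to 40 there (at least 8.31-fold lower). In A549 miR-539 went from 40 to 31.5 (at least 9.90-fold higher), and in PC9 the dme-miR-7 assay went from 36.2 to 31.6 (at least 8.36-fold higher). In PC3 there were 0.

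These counts depended on the normalizer. In PC9 45 assays were 2-fold higher and 0 lower with U6 in place of the mean of microRNAs, and in LC2/ad 15 were higher and 18 lower with all control RNAs and 28 higher and 4 lower with the median. In PC9 the microRNAs gained 0.72 (log2) against U6, and 0.58 against RNU44 and RNU48 (SD 0.06 over 4 wells), while in A549, LC2/ad and PC3 the values against RNU44 and RNU48 were 0.11, -0.29 and -0.12. In the authors' deposited table, 124 of 754 assays were at least 2-fold higher in PC9 and 48 lower, and 67 of these rested on a sample in which the assay did not amplify.

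The 14q32 microRNAs lie between DLK1 and DIO3, an imprinted region of chromosome 14, where all 46 microRNA genes behind the 62 assays of the list were placed. After TGF-β1, 11 of the 16 members with a value in LC2/ad were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 change of 2.08, at percentile 100 of matched random lists. The median was 2.23 over the 12 of these on card A and -0.13 over the 4 on card B, which went both ways. miR-409-3p went from a Ct of 32.7 to 29.2 there (log2 3.69), miR-379 from 34.2 to 31.0 (3.64) and miR-495 from 34.6 to 31.8 (3.21), whereas miR-432# had -1.23 and miR-432 was detected only in the control sample. In A549 5 of 10 members were at least 2-fold higher, with a median of 0.91 at percentile 99.68, and miR-409-3p and miR-539 were detected only after TGF-β1. With a Ct limit of 32 the A549 median was -0.26, over 3 members. In PC3 all 4 members with a value were higher (median 0.88), and in PC9 miR-494 alone was detected, at -0.67, or 0.23 when scaled to U6. In the same LC2/ad samples the fibroblast and smooth muscle markers miR-145, miR-143 and miR-199a-3p also lay higher (median 2.20), while miR-214 did not amplify in either. The number of members detected went from 5 to 9 in A549, 12 to 14 in LC2/ad, 2 to 4 in PC3 and 1 to 1 in PC9.

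Of the 3 microRNAs in the series title, miR-134 was detected only in LC2/ad after TGF-β1, where its Ct went from 36.6 to 32.6 (at least 7.00-fold higher). In A549 its Ct went from 40 to 35.1, just outside the limit. miR-487b went from 38.4 to 32.5 in LC2/ad (at least 7.35-fold higher) and from 37.8 to 34.4 in A549 (at least 1.25-fold higher). miR-655 stayed above the limit throughout, with Ct values of 40 and 38.8 in A549 and 40 and 35.8 in LC2/ad. None of the 3 amplified in PC3 or PC9. The authors' deposited table gives folds of 30.2, 10.2 and 2.40 for miR-134, miR-487b and miR-655 in A549, and of 16.9, 59.2 and 19.7 in LC2/ad, all against control samples above the limit. It also lists 1.59 for each of them in PC9, the value that assays not amplified in either sample take from the U6 scaling on that card.

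**Figure D2:**
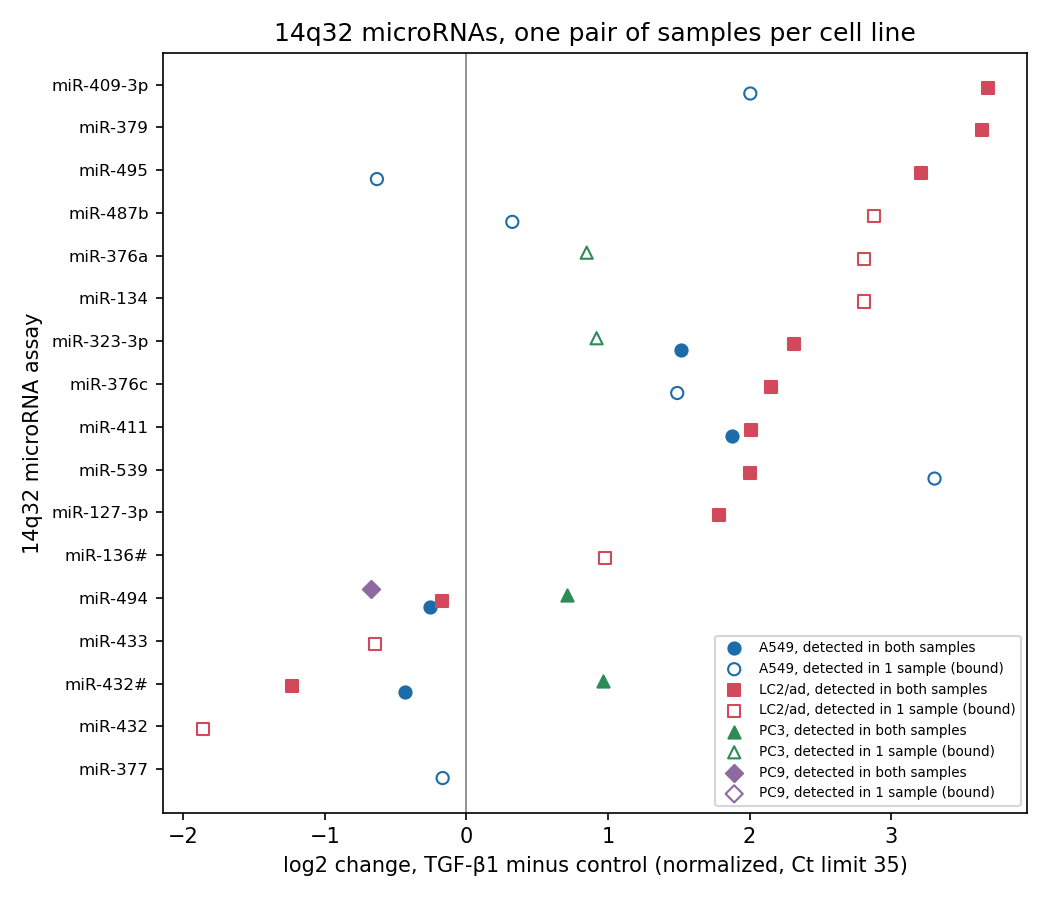
Log2 change after TGF-β1 (x axis) of the 17 assays of the 14q32 list detected in any sample (y axis, ordered by the LC2/ad value), with 1 point per cell line; filled points were detected in both samples and open points in 1, so that their size is a bound. The LC2/ad points reach 3.69 for miR-409-3p, and PC9 has a point for miR-494 only.

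The responses of the lines were compared across assays at Ct 32 or below in all 4 samples of a pair, where assays are not independent replicates. A549 and LC2/ad had the highest correlation of log2 changes (Pearson r = 0.50, Spearman rho = 0.39, 150 assays), followed by A549 and PC9 (r = 0.37, 119 assays) and LC2/ad and PC9 (r = 0.30, 121 assays). With PC3 the correlations were 0.01 for A549, 0.03 for LC2/ad and 0.01 for PC9. The share of assays with the same sign was 65.5% for A549 and PC9, 62.7% for A549 and LC2/ad, 62.0% for LC2/ad and PC9 and 49.6% for A549 and PC3. The lines share no control samples.

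Of 372 assays, 240 differed in level between lines (limma F test, adjusted for 372 tests). Undetected assays were set to the limit of their own sample, which lies higher in PC9 after normalization, so this count includes such offsets. With 1 limit for all samples of a card, 191 of 318 assays differed, and 24 of the 240 lay under that limit in all samples. miR-200c was highest in PC9, 6.79 log2 units above that line's normalizer, with 2.05 in PC3, -3.45 in A549 and -3.96 in LC2/ad, and its partner miR-141 was also highest in PC9 (0.19). miR-205, an epithelial microRNA, was detected in PC9 alone, and miR-146a was highest there too (5.79, against 0.35 in A549 and -2.87 in PC3). PC3 stood out by miR-214 (1.87) and miR-199a-3p (2.23), both abundant in fibroblasts, and by miR-10b (2.32) and miR-10b# (1.28). miR-34a, a p53 target, was detected in all lines but PC3, and so was miR-886-5p, now annotated as part of a non-coding RNA rather than a microRNA. miR-192 was highest in A549 (5.28) and LC2/ad (4.28), and miR-598 was detected in PC3 and PC9 but not in A549 or LC2/ad. All these 12 had adjusted p values of 9.11e-05 or less, and of 0.000145 or less with 1 limit for all samples of a card. With no replicate culture of a line under either condition, these p values and the counts between lines rest on the spread left after line and treatment. They do not measure the spread between cultures of a line.

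A549 and LC2/ad were close to each other, with 6 assays past the threshold between them, against 148 to 201 for the other 5 pairs of lines. With 1 limit for all samples of a card the counts were 3 and 124 to 152, and among assays detected in all samples 1 and 86 to 111. Over 110 assays at Ct 32 or below in all samples, their levels differed with an SD of 0.53 (log2), where the other pairs had 1.70 to 2.18. Between single samples the SD for A549 and LC2/ad was 0.62 in the control samples and 0.61 after TGF-β1. The SD of the change after TGF-β1 was 0.54 within A549, 0.72 within LC2/ad, 0.29 within PC3 and 0.46 within PC9. Of these 110 assays, 8 differed more than 2-fold between A549 and LC2/ad. miR-127-3p, of the 14q32 cluster, was at 40 in both A549 samples and at 31.8 and 30.4 in LC2/ad.

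**Figure D3:**
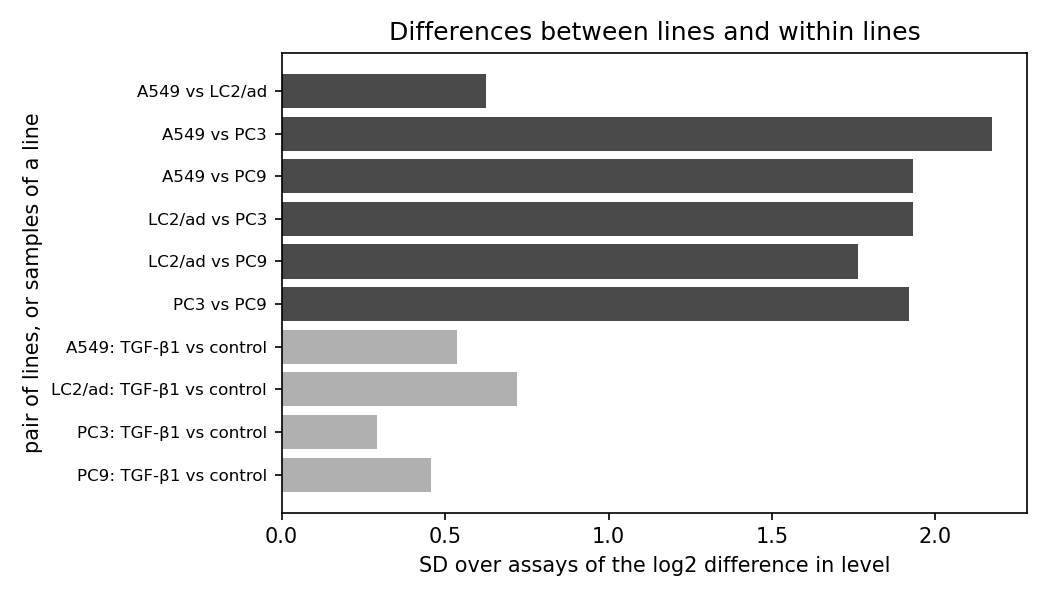
Standard deviation over 110 assays of the log2 difference in level (x axis) for the 6 pairs of cell lines (dark bars, control samples) and for TGF-β1 against control within each line (light bars). The bar of A549 against LC2/ad, at 0.62, lies between the A549 bar for TGF-β1, at 0.54, and that of LC2/ad, at 0.72, and the other pairs lie at 1.76 or more.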

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

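All tests weighed in this part were chosen after the results were seen. Of 30 groups of 4 samples searched for a single distant value, 2 held one, where chance gives 1.5. Both were the TGF-β1 sample of PC9, with 149 assays at Ct 32 or below, fewer than the other 3 treated samples, and an RNU44 Ct on card A of 25.1, later than theirs. The PC9 control sample lay on the same sides of the other controls, with 140 assays and a Ct of 24.8.

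The changes of PC9 moved with the normalizer, in that the microRNAs gained on the control RNAs after TGF-β1. Noise of the U6 wells alone is argued against, because the gain held at 0.58 (log2) against RNU44 and RNU48, with an SD of 0.06 over 4 wells. Less RNA in the treated sample is argued against as the whole source, because the mean microRNA Ct changed by -0.28 over both cards, that is, the microRNAs came up earlier. A real rise of microRNAs relative to small nuclear and nucleolar RNAs in PC9, or a difference in how the 2 RNA preparations kept each class, stays open and untested, with 1 pair of samples.

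In LC2/ad the 14q32 microRNAs lay higher after TGF-β1 as a group, with a median of at least 1.70 over 4 kinds of normalizer. Scatter of assays near the detection limit is argued against, since the median of the 14 members left without those in the series title, 2.01, lay at percentile 100 of random lists of the same level. A fault of 1 card stays open, since the median was 2.23 over 12 members on card A and -0.13 over 4 on card B, too few and too mixed to decide, with miR-409-3p at 3.69 and miR-432# at -1.23. Fibroblasts or smooth muscle cells in the treated sample stay open, since miR-199a-3p appeared at a Ct of 34.5 while miR-214 stayed at 40, and how much of each such cells would bring is not in these data. That TGF-β1 raises part of this cluster in LC2/ad is a hypothesis, since any other difference between 2 single cultures is untested, and the study named members of this list from these samples.

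A549 and LC2/ad had closely similar levels, and a single column deposited for both is argued against, with 1 amplified assay of identical Ct in the 2 control samples. Cells of 1 culture in both stay open by the test. The 6 assays that differed past the threshold fell to 3 with a single detection floor, to 1 with the deposited ratio and to 1 among assays detected in all samples, a filter that drops 5 of the 6. Some values go against 1 culture. miR-95, miR-886-5p and miR-224 (named after their values were seen) were higher in A549 by a log2 of 2.66, 1.99 and 1.79, past the threshold with that floor too. With the control RNAs miR-886-5p and miR-224 were not past it (adjusted p = 0.0690 and 0.0885, limma), and with the deposited ratio none of these was. miR-127-3p was at 40 in both A549 samples and at 31.8 and 30.4 in LC2/ad. It passed with the deposited ratio but not with the single floor (adjusted p = 0.126, limma). What SD 2 sublines of 1 origin would give is not in these data. The SD between the control samples of A549 and LC2/ad was 0.62 and between their treated samples 0.61, while no other pair was under 1.72. These lie below the 0.72 within LC2/ad but above the 0.54 within A549, both of which include the change after TGF-β1. Sublines of 1 origin and distinct lines that happen to be alike both stay open, and these data hold no genetic marker to separate the 2. If the lines are related, they count as fewer than 4 independent lines.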

How the results depend on the processing

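The averaging of A549 and LC2/ad and the single detection floor were chosen after seeing the data, all other settings before. The count of assays past the threshold over the lines was 0 under all settings but U6 alone, which gave 2, with leave-one-line-out counts of 0 to 0 (limma). Without the block by line it was also 0, with 0 assays at an unadjusted p under 0.05, against 30 in the paired fit. The fit without the block keeps the differences between lines in its spread, so its count of 0 could hardly have been otherwise. The mean of miR-141, -0.02 in the paired fit, was 0.0875 without the block. That fit also took in LC2/ad, where neither sample detected miR-141, at the limits of its control and treated samples, -7.52 and -7.12 after normalization. The mean of miR-141 also turned positive with the control RNAs (0.21), U6 (0.45), RNU48 (0.11) and the median normalizer (0.00308). Averaging A549 and LC2/ad gave 0 assays, 12 at an unadjusted p under 0.05 and 1 list. The cause of the other shifts was not tested.

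For the 32 of 35 splits of the 8 samples that could be fitted with the line as a block, 32 gave as many assays past the threshold, since the real count and the highest other were both 0. At an unadjusted p under 0.05 the real split had 30 assays and the highest of the other 7 splits that part all pairs had 21, with 1 of 8 as large, too few splits for a share under 0.05. Splits that part only 2 pairs reached up to 49 such assays, more than the real split. As many lists past the threshold as the real 1 came from 18 of 32 splits, with a highest other of 3, so chance is not excluded for the miR-23, miR-27 and miR-24 list.

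The lists were run with the other normalizers per card, the deposited ratio, Ct limits of 32 and 38, no block, left-out lines and the averaged lines. Their number past the threshold was 1 except without LC2/ad, where it was 2, for a range of 1 to 2 over the left-out lines; let-7 then passed (0.39 above all assays, adjusted p = 0.0318, or 0.689 with an estimated correlation). Relative to all assays, the let-7 mean ranged from -0.00293 to 0.39 over the left-out lines and that of the TGF-β list from -0.16 to 0.0392, with 0.20 at a Ct limit of 38 and -0.37 with the deposited ratio. The left-out lines gave 0.27 to 0.60 for miR-29, 0.18 to 0.51 for the miR-183 cluster and 0.31 to 0.84 for miR-200 with miR-205 (over 3 to 5 assays), and the deposited ratio 1.07, 0.0925 and 0.88. That of the miR-15 and miR-16 list ranged from -0.14 to 0.0611, with -0.00662 for U6, -0.00861 for the median, -0.26 for the deposited ratio, -0.13 at a limit of 32, -0.16 at 38 and -0.000458 with the 2 lines averaged. The miR-23, miR-27 and miR-24 list stayed past the threshold in each of these settings with the preset correlation, at 0.53 to 0.86 over the left-out lines, and the call was lost in each with an estimated one (adjusted p = 0.372 to 0.848).

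Counts of 2-fold changes within lines moved most. With the control RNAs, A549 had 14 higher, LC2/ad 15 higher and 18 lower, PC3 1 lower, and PC9 26 higher and 0 lower. With U6 and with the deposited ratio alike, A549 had 14 higher, LC2/ad 16 higher and 15 lower, PC3 3 higher, and PC9 45 higher and 0 lower. RNU48 gave LC2/ad 16 higher and 14 lower, PC3 1 lower and PC9 22 higher and 0 lower, and the median gave A549 13 higher, LC2/ad 28 higher and 4 lower, and PC9 4 higher and 6 lower. A counting limit of 30, which leaves fewer assays, gave 4 higher and 1 lower in A549, 11 and 5 in LC2/ad, 0 higher in PC3, and 3 and 0 in PC9. A limit of 35 gave 19 and 17 in A549, 40 and 23 in LC2/ad, 9 and 11 in PC3, and 19 and 13 in PC9. The authors' deposited folds over all assays gave 85 and 66, 79 and 96, 66 and 68, and 124 and 48, of which 66, 72, 80 and 67 rested on a sample in which the assay did not amplify.

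Assays that differed between lines fell from 240 to 149 with the deposited ratio and 132 when only assays detected in all samples were tested, and those between A549 and LC2/ad from 6 to 1 in both. A single detection floor gave 191 and 3. Of the 240, 54 passed only without that floor. The 240 include undetected assays that differ by the offset of their sample's limit, and 24 of them lay under the floor in all samples. The floor also shrank differences of detected assays, as for miR-127-3p between A549 and LC2/ad, from a log2 of -3.86 to -2.46. The A549 median of the 14q32 list reversed to -0.26 at a Ct limit of 32, which leaves 3 members; in LC2/ad it was 1.28 to 2.35 throughout. The median correlation of responses was 0.17, and 0.12 to 0.31 otherwise. Values near the Ct limit rest on few template copies, which bears on the 14q32 members, 10 of which had a value in A549 at the limit of 35.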

Other observations

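miR-143 and miR-145, a pair transcribed together and abundant in fibroblasts and smooth muscle, had a value in LC2/ad and PC9 only. In LC2/ad miR-143 went from a Ct of 33.7 to 31.9 (log2 2.20), and in PC9 miR-145 went from 36.4 to 32.3 (at least 5.49-fold higher), while miR-143 went from 40 to 34.6 (at least 1.14-fold higher). With the median normalizer the PC9 bound of miR-143 turned negative, which is not a fall, since miR-143 was detected there only after TGF-β1. In LC2/ad the 3 fibroblast and smooth muscle markers with a value had a median of 2.20, at percentile 96.5 of matched lists, but miR-214 was not detected there, and miR-199a-3p was at 34.5 after TGF-β1. In PC3 miR-199a-3p and miR-214 were at 25.1 and 25.7 in the control sample, with log2 changes of -0.12 and 0.37, and the 4 markers with a value had a median of 0.42, at percentile 99.69, or 0.28 with the control RNAs and 0.215 with RNU48.

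Of the other marker lists, 4 of 10 blood assays, 1 of 8 muscle assays, 3 of 4 neural assays, 2 of 2 endothelial assays and 0 of 2 liver assays were detected in any sample. Of 45 C19MC assays 7 were detected in any sample, and those with a value had medians of -0.30 in PC3 (4 assays) and -0.23 in PC9 (3 assays). The miR-34 list had medians of 0.29 in A549, -0.19 in LC2/ad and 0.28 in PC9, and the miR-146 list one of 0.30 in PC3.

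The largest fold of each line in the authors' deposited table belongs to an assay at 40 in the control sample. It is 379 for miR-539 in A549, 417 for miR-135b in LC2/ad and 116 for miR-508-3p in PC3, and in PC9 it is that of miR-579. Assays that amplified in neither sample are listed there at 1.59-fold on card A and 1.15-fold on card B in PC9.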
